A study of mouse gut metagenome with 30 samples.

How the data were processed

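Bacterial 16S ribosomal RNA gene fragments were sequenced from the ascending and the descending colon of 15 female mice, which gave 30 samples. Per the labels' protocols, DNA was extracted with a ZymoBIOMICS kit and bead beating, the V4 region was amplified with the primers 515f and 806r, and paired reads of 250 bases were taken on an Illumina HiSeq. Per the submitters' processing notes, the reads were demultiplexed with bcl2fastq 2.17. The program that called the amplicon sequence variants (ASVs), its filters and the taxonomy database are not given in the sources used here. The deposited table holds counts of reads per ASV and sample, without normalization, as its whole numbers and its unequal totals per sample show. It lists 370 ASVs of 250 to 252 bases with their sequences and taxonomy, of which 242 carry a genus name. The table falls into 7 phyla, 29 families and 78 taxa at genus level, where an ASV without a genus name was kept under its lowest named rank.

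Total counts per sample ran from 3887 to 117276, with a mean of 47852 ± 24737 (SD, n = 30), and 1435562 counts were used in all. The smallest count above 0 in a sample lay between 2 and 6, so a count of 1 is never listed. A count of 0 was therefore read as up to 3 counts in each library. Intervals for the share of a single sample are 95% Wilson intervals. Intervals and floors cover counting error only, since reads from a polymerase chain reaction are not independent molecules. No column of the table was left out.

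Samples were grouped by the titles in the labels into control and mutant mice, into ascending and descending colon, and into the 3 cages A, B and C. Mice are named by genotype, cage letter and number, so that control A1 is the mouse titled control 1 of cage A. Sample codes showed that both regions came from the same 15 animals. The codes of mouse 12, which is mutant C2, go against its titles: the code of its descending sample names the cecum, and the code of its ascending sample names the distal colon. The titles were kept, and an exchange of these 2 samples was run as an alternative. Mice with 1 number in the control and mutant group of a cage are different animals. Their profiles, centred within cage and genotype, correlated with r between -0.299 and 0.252 and a median of -0.111, and 1 of 12 pairs passed 0.1. The numbers thus pair no animals, and a fit with the replicate number as a block was run as an alternative only.

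ASV and genus counts were compared with edgeR 4.0.16 in R 4.3.3, with TMMwsp factors, a quasi-likelihood fit and Benjamini-Hochberg adjusted p under 0.05. ASVs entered a fit with at least 20 counts in all and counts in at least 4 of the samples fitted. Genotype was fitted beside cage, in each region and on the sum of both regions per mouse. The region was fitted within mouse, as an effect in control mice, an effect in mutant mice and the difference of these 2 effects. Cages were compared by an F test beside genotype, and a genotype by cage term was tested by an F test. Fold changes are given with the standard error (SE) of the log2 value.

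Shares of phyla, families and taxon lists were compared for taxa with a mean share of at least 0.1%. Genotypes were compared by an exact two-sided permutation test of the genotype term beside cage, over all 1000 relabellings within cages, whose smallest p is 0.001. Regions were compared by an exact two-sided sign-flip test within mouse over 32768 arrangements for 15 mice, 128 for the 7 control mice and 256 for the 8 mutant mice. Benjamini-Hochberg adjustment was made within rank and comparison. Bray-Curtis distances of shares were split by PERMANOVA, exact for genotype and over 100000 permutations for cage. The Shannon index used natural logarithms, and ASV richness is the number expected at 3887 counts. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps.

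The groups, comparisons, tests, taxon lists, alternatives and the rule for named taxa were fixed before the data were examined. The rule took, for each comparison of ASVs or genera, the 12 with the smallest p that rose and the 12 that fell among those past the threshold, and the 3 with the smallest p where fewer than 3 passed. It also took every phylum, the 10 families, genera and ASVs with the highest mean share, and list members that passed. The lists were mucin glycan users, the S24-7 family (Muribaculaceae), butyrate-associated Clostridia (Lachnospiraceae and Ruminococcaceae), Clostridiales without a family name, lactic acid bacteria, the Erysipelotrichaceae group, colitis-associated facultative anaerobes, sulfate reducers, mucus-dwelling spiral bacteria, Rikenellaceae, Prevotellaceae, the Sutterella group, Mollicutes, segmented filamentous bacteria, signs of diet or host DNA, and reagent bacteria. The table held 0 ASVs of the lists of sulfate reducers, mucus-dwelling spiral bacteria, Prevotellaceae, segmented filamentous bacteria and Clostridiales without a family name.

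Alternatives were TMM factors, total counts alone, DESeq2 1.42.0 with poscounts size factors, no filter, a stricter filter of 100 counts in all, no cage term, the replicate block, fits without the mouse block, each cage alone, counts thinned to 3887, other distances, the centred log ratio with 0.5 added, the exchange of the samples of mouse 12, and each mouse left out. For taxon lists, the log ratio of the list to all other counts took the place of the centred log ratio. A fit without the mice of the 2 libraries under 10000 counts was added after the data had been seen. The models were tested on simulated data drawn from the fitted means and dispersions without a group effect, with 40 changed ASVs in each of 24 runs. In the ascending colon 16.1% of simulated 4-fold changes and 52.9% of 16-fold changes were called, and 12.2% of the calls (44 of 362) were false. In the descending colon these shares were 8.30%, 47.6% and 8.21% (23 of 280). Between regions of control mice 8.14% of 2-fold and 33.5% of 4-fold changes were called, and 7.21% of the calls (15 of 208) were false. The share of false calls thus lay above the nominal 5% in each design. In runs with no change, 4 of 24 gave a call in the ascending design, and 1 of 24 gave one in each of the others. The exact permutation tests passed p under 0.05 in 3.6% and 5.6% of 500 simulated sets without a change.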

Results

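The 16S V4 amplicon profiles of 30 samples covered the ascending and the descending colon of 15 female mice. The mutant mice carried a deficiency of mucin-type O-glycans, the sugar chains of intestinal mucus, made by tamoxifen-induced deletion of C1galt1 under Villin-Cre on a C3GnT-deficient background. Per the labels, tamoxifen was given at 0.5 mg per day (about 20 mg/kg) for 5 days, and mice were analysed 5 or 10 days later, with the interval of each mouse not given. The 7 control and 8 mutant littermates shared 3 cages of 5 mice, with 2 control and 3 mutant mice in cage A, 3 and 2 in cage B, and 2 and 3 in cage C. The strain tag reads C57BL/6 for cage A, while cages B and C were of mixed background. Ages were labelled 3.4 for cage A, 2.6 for cage B and 3.2 for cage C without a unit. Cage, age and, for cage A, the strain tag could not be told apart. The extraction protocol names fecal samples, while the sample labels name the 2 colon regions. The titles tag the mutant samples of both regions TMDKOAsc, so the ending Asc does not follow the sampled region. The titles do not explain this ending, and the loss of glycans in each region was not measured in these data. The same tamoxifen dose is listed for control and mutant samples. Ascending samples held 13683 to 71035 counts in control mice (mean 52823 ± 22168, SD, n = 7) and 7318 to 117276 in mutant mice (54002 ± 37403, n = 8). Descending samples held 38191 to 72021 counts in control mice (53209 ± 12330, n = 7) and 3887 to 57094 in mutant mice (32664 ± 14974, n = 8).

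Firmicutes and Bacteroidetes made up most of the counts in every group. In control mice, Firmicutes held 58.6% ± 7.99 (SD, n = 7) of the ascending and 49.0% ± 13.0 of the descending counts. In mutant mice they held 52.8% ± 8.77 (n = 8) and 47.0% ± 6.07. Bacteroidetes held 31.6% ± 6.95 and 39.3% ± 9.47 in control mice, and 41.6% ± 8.60 and 47.5% ± 7.26 in mutant mice. Over all samples the family with the highest mean share was Muribaculaceae (35.4%), common polysaccharide-degrading bacteria of the mouse gut, with 28.5% ± 6.90 of the ascending counts in control mice and 35.6% ± 8.06 in mutant mice. Lachnospiraceae, anaerobes that include butyrate producers, had a mean of 24.01% over all samples, with 29.3% ± 9.46 of the ascending counts in control mice, above Muribaculaceae, and 24.8% ± 11.3 in mutant mice. ASV1 of the Muribaculaceae had the highest mean share of all ASVs over all samples, followed by other Muribaculaceae (ASV4, ASV3 and ASV6), Faecalibaculum (ASV5), Lactobacillus (ASV2), Akkermansia (ASV7), Alistipes (ASV9), Coriobacteriaceae_UCG-002 (ASV8) and Clostridium_sensu_stricto_1 (ASV10).

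The first comparison asked how the microbiota of O-glycan mutants differed from that of their control littermates. In the ascending colon, Erysipelatoclostridium was 17.0-fold higher in mutant mice (log2 4.09 ± 0.58, SE, n = 7 and 8), with a share of 0.0268% ± 0.0256 in control and 0.411% ± 0.322 in mutant mice. Ruminococcaceae_UCG-014 was 12.9-fold higher (log2 3.69 ± 0.78) and rose from 0.250% ± 0.212 to 2.23% ± 1.37 of the counts. Bacteroides, a genus with many glycan degraders, was 6.04-fold higher (log2 2.59 ± 0.59) and Ruminococcus_1 was 3.21-fold higher (log2 1.68 ± 0.50). Akkermansia, a mucin-degrading genus of the mucus layer, was 3.55-fold lower (log2 -1.83 ± 0.50), with 4.63% ± 7.29 of the counts in control and 0.997% ± 0.559 in mutant mice. Turicibacter was 5.99-fold lower (log2 -2.58 ± 0.84) and Eisenbergiella, a member of the Lachnospiraceae, was 9.21-fold lower (log2 -3.20 ± 0.71). For these 7 genera, the mean of the mutant mice lay on the same side of the control mean in all 3 cages. The size could differ between cages: the Bacteroides share differed by 2.41 percentage points in cage A, 2.59 in cage B and 0.765 in cage C. Single mice overlapped, as with Bacteroides at 3.825% in control C2 and 2.194% in mutant C1.

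By edgeR, 12 of 67 genera passed the threshold in the ascending colon, 8 higher and 4 lower in mutant mice. Erysipelatoclostridium had the smallest adjusted p (6.83e-05), followed by Ruminococcaceae_UCG-014 and Eisenbergiella (0.00485), Bacteroides (0.00632) and Akkermansia (0.0205), with Ruminococcus_1 at 0.0317 and Turicibacter at 0.0403. The others that rose were Christensenellaceae without a genus name, Christensenellaceae_R-7_group, Erysipelotrichaceae without a genus name and Marvinbryantia, with adjusted p from 0.0145 to 0.0477. Christensenellaceae_R-7_group was found in 2 control and 3 mutant samples, and cage C held all of them. Ureaplasma, a genus of the Mollicutes, was 8.24-fold lower and had counts in 5 of 7 control samples and 1 of 8 mutant samples (adjusted p = 0.0317); without that sample, mutant C3, the mutant group had 0 counts and was at least 1.60-fold lower with a floor of 3 counts per library. Leaving out 1 mouse also moved the log2 difference of Erysipelatoclostridium to 4.75 (control A2), Ruminococcaceae_UCG-014 to 3.01 (mutant C2), Akkermansia to -1.18 (control C2) and Turicibacter to -3.44 (mutant C3), and these 4 still passed there. With each of the 15 mice left out in turn, Erysipelatoclostridium, Ruminococcaceae_UCG-014, Bacteroides, Akkermansia and Eisenbergiella passed in 15 fits, Christensenellaceae without a genus name in 14, Christensenellaceae_R-7_group in 10, Ruminococcus_1 in 9, Ureaplasma and Erysipelotrichaceae without a genus name in 8, Turicibacter in 7 and Marvinbryantia in 4, with adjusted p up to 0.174 where a call ended. With the replicate number as a block, which pairs no animals, 3 genera passed. DESeq2 called 6 of the 12, without Ruminococcus_1, Ureaplasma, Marvinbryantia, both Christensenellaceae groups and Erysipelotrichaceae without a genus name. The count fell to 7 without control B1, control B2 or mutant B1, to 6 without mutant B2, and to 7 without the mice of both libraries under 10000 counts.

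At the level of single sequences, 9 of the tested ASVs passed in the ascending colon, 7 higher and 2 lower in mutant mice. ASV86 of Erysipelatoclostridium was 17.1-fold higher (log2 4.09 ± 0.69, adjusted p = 0.00175). ASV191 and ASV132 of the same genus, ASV31 and ASV32 of Ruminococcaceae_UCG-014, ASV11 of Bacteroides and ASV15 of Ruminococcus_1 were 4.55-fold to 30.7-fold higher (adjusted p 0.0358 to 0.0382). ASV92 of A2 was 42.5-fold lower (log2 -5.41 ± 1.28) and ASV26, the Eisenbergiella sequence, was 10.2-fold lower (log2 -3.35 ± 0.83), both with an adjusted p of 0.0358. Of the mutant samples, mutant C2 alone had counts of ASV92, and without it ASV92 was at least 26.5-fold lower with a floor of 3 counts per library, while its log2 difference was -6.16 without control C2. Control B1 alone of the control samples had counts of ASV191, which was at least 8.34-fold higher without it, with the same floor, and had a log2 difference of 4.26 without control B2, where it did not pass. Without control A2 the log2 difference was 5.98 for ASV31 and 5.42 for ASV132, which then did not pass (adjusted p = 0.0518), and that of ASV32 was 5.97 without control B3, 5.63 without mutant B1 and 3.896 without mutant C2. In these fits ASV92 passed in 8 of 15, ASV31 and ASV191 in 7, ASV11, ASV26 and ASV132 in 6, ASV32 in 5 and ASV15 in 3. Cage C held no counts of ASV31 or ASV132, so their differences come from cages A and B. DESeq2 called 12 ASVs but gave no adjusted p for ASV191 and ASV132, and the replicate block gave 0 by edgeR, with 20 ASVs at an unadjusted p under 0.05. Leaving out 1 mouse gave 1 ASV without control A1, B2 or C1 or mutant A1 or A2, 2 without control A2 or mutant B2, and 4 without control B1 or B3; ASV86 passed in each of these 15 fits.

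In the descending colon of the same mice, Turicibacter was 16.1-fold lower in mutant mice (log2 -4.01 ± 0.78, SE, n = 7 and 8), with 3.97% ± 4.27 of the counts in control and 0.132% ± 0.0830 in mutant mice. Bifidobacterium, a genus of saccharolytic gut bacteria, was 8.62-fold lower (log2 -3.11 ± 0.81) and fell from 1.62% ± 1.03 to 0.406% ± 0.413. Akkermansia was 4.64-fold lower (log2 -2.21 ± 0.61) and Eisenbergiella 5.89-fold lower (log2 -2.56 ± 0.77). Erysipelatoclostridium was 6.74-fold higher (log2 2.75 ± 0.63), with 0.0563% ± 0.0286 in control and 0.570% ± 0.515 in mutant mice. The means of these 5 genera also lay on the same side in all 3 cages. The difference in mean Turicibacter share was -7.99 percentage points in cage B, -1.28 in cage C and -0.183 in cage A.

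Of 63 genera, 7 passed by edgeR in the descending colon, and Erysipelatoclostridium alone of them was higher in mutant mice. Adjusted p was 0.00544 for Turicibacter, 0.0137 for Erysipelatoclostridium, 0.0255 for Bifidobacterium, 0.0284 for Akkermansia and 0.0386 for Eisenbergiella. Faecalibaculum, of which cage A held nearly all counts, was 3.63-fold lower (adjusted p = 0.0424). Bacteroides was 3.645-fold higher in mutant mice and did not pass (adjusted p = 0.0607 by edgeR). Ureaplasma had counts in 7 of 7 control samples, with 0.0290% ± 0.0281, and 0 counts in 8 mutant samples (adjusted p = 0.0255), at least 1.69-fold lower with a floor of 3 counts per library. DESeq2 called 12 genera, among them 6 of the 7, and gave no adjusted p for Ureaplasma, and the replicate block gave 4. Turicibacter had a log2 difference of -4.66 without control A1 and Eisenbergiella of -3.16 without mutant A1. Turicibacter passed in 15 of the 15 fits with a mouse left out, Erysipelatoclostridium in 14, Bifidobacterium in 12, Ureaplasma in 11, Akkermansia in 10, Eisenbergiella in 6 and Faecalibaculum in 5, with adjusted p up to 0.1603 where a call ended. The count was 4 without control A2 or mutant C3 and 2 without control B2, control C1 or mutant B1.

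Among descending ASVs 4 of 245 passed: ASV13, the Turicibacter sequence, was 17.0-fold lower (log2 -4.08 ± 0.80, adjusted p = 0.0120), ASV86 was 6.23-fold higher (log2 2.64 ± 0.62, adjusted p = 0.0330) and ASV31 was 16.5-fold higher (log2 4.04 ± 0.90, adjusted p = 0.0330). ASV191 of Erysipelatoclostridium had 0 counts in 7 control samples and 0.0716% ± 0.0865 in the mutant group (n = 8), at least 12.1-fold higher with a floor of 3 counts per library (adjusted p = 0.0376). ASV86, ASV31 and ASV191 passed in both regions by edgeR. Cage C held no counts of ASV31, so its difference comes from cages A and B. Of 10 ASVs called in either region and tested in both, 10 moved in 1 direction. Of 14 genera called in either region and tested in both, 13 moved in 1 direction, among them the 5 called in both (Erysipelatoclostridium, Turicibacter, Akkermansia, Eisenbergiella and Ureaplasma), and Marvinbryantia did not (log2 1.38 and -0.08), though the regions come from the same mice and are not independent. With both regions summed per mouse, ASV86 (8.16-fold, log2 3.03 ± 0.51, adjusted p = 0.00649) and ASV191 passed among 288 ASVs. Without control A1 the descending log2 difference of ASV13 was -4.71, and without control A2 that of ASV31 was 6.11. ASV92 of A2 came next in the sum and did not pass (adjusted p = 0.0577). With a mouse left out, the descending calls held in 13 of 15 fits for ASV13, 9 for ASV31, 8 for ASV86 and 6 of the 11 that gave a value for ASV191, and the summed calls in 15 for ASV86 and 13 for ASV191. DESeq2 called 6 ASVs in the descending colon, among them ASV13 and ASV86 but neither ASV31 (adjusted p = 0.113) nor ASV191 (0.123), and 10 in the sum, among them ASV86 and ASV191, and the replicate block gave 0 by edgeR in both, with 23 and 25 ASVs at an unadjusted p under 0.05. The descending count was 0 without mutant B1 or B2, 1 without control A1, B1 or B2, 2 without control A2 or B3, and 8 without control C2, and the summed count was 1 without control B1 or B2, 4 without mutant C3 and 5 without control C2.

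**Figure D1:**
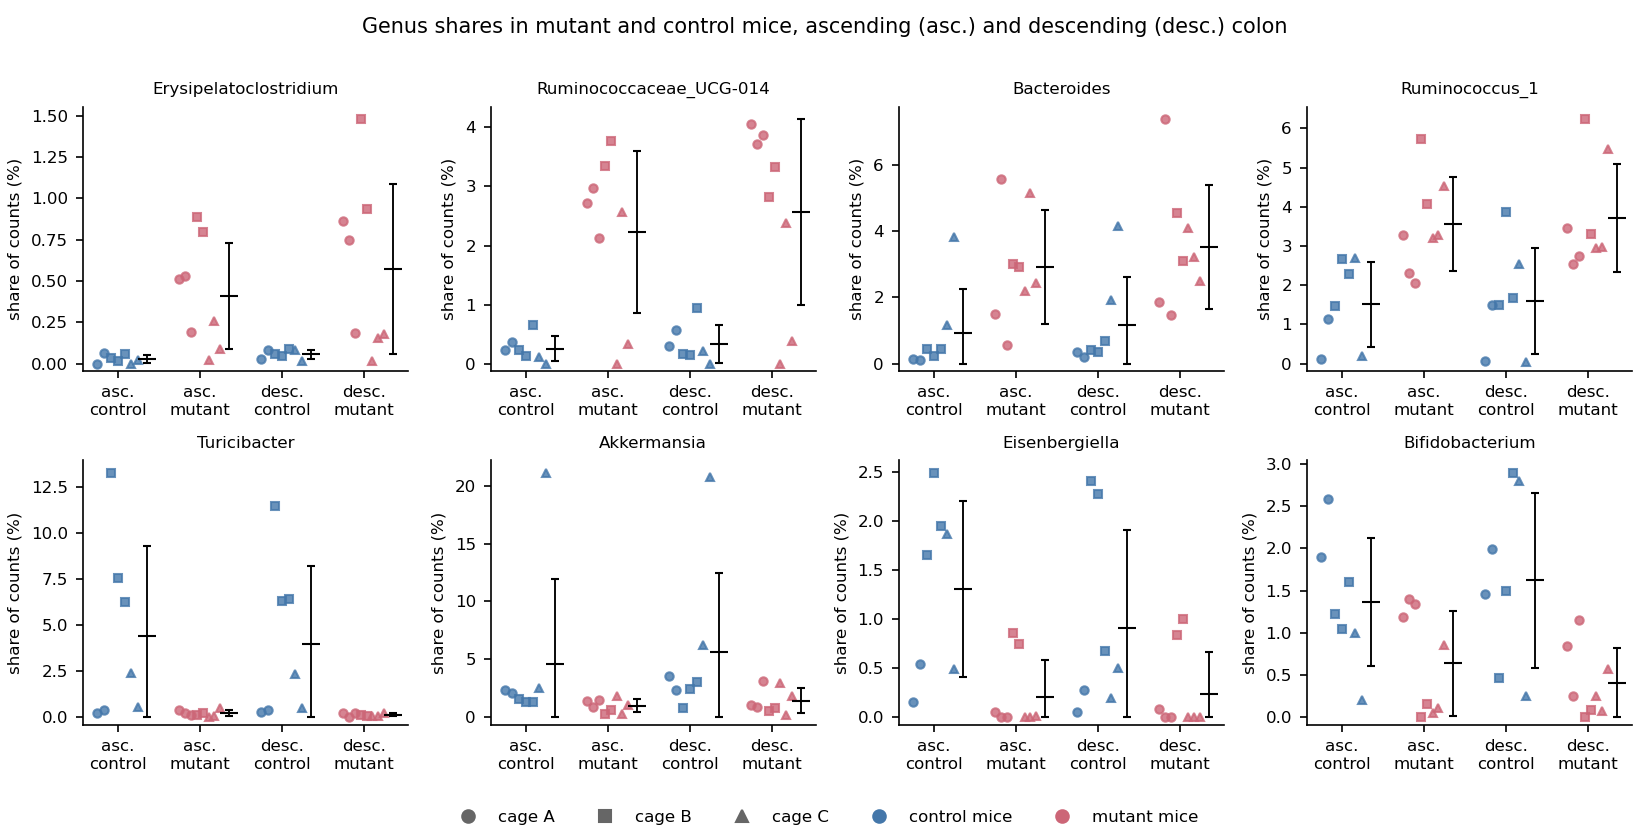
Share of counts (%, linear axis) of 8 genera in each sample, by region and genotype, with the cage as the symbol; the bar beside each group is the mean ± SD (7 control or 8 mutant mice, lower end drawn at 0 where the SD exceeds the mean). Erysipelatoclostridium averaged 0.0268% in ascending control and 0.411% in ascending mutant samples, and Turicibacter averaged 4.39% and 0.218%.

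Family shares gave the same comparison in percent of all counts. Ruminococcaceae, which include cellulose and starch degraders, were higher in mutant mice by 4.26 ± 0.81 percentage points (SE, 15 mice) in the ascending and 5.12 ± 1.25 in the descending colon. Akkermansiaceae fell by 4.23 ± 2.52 and 4.85 ± 2.27 points, and with them the phylum Verrucomicrobia, which they made up. Erysipelotrichaceae fell by 6.51 ± 1.97 and 6.76 ± 2.08 points, and Bifidobacteriaceae fell by 0.80002 ± 0.208 and 1.26 ± 0.42 points. The genus Bifidobacterium did not pass by edgeR in the ascending colon (log2 -1.41 ± 0.72, adjusted p = 0.208). Within the Erysipelotrichaceae, Turicibacter was lower and Erysipelatoclostridium was higher in mutant mice, so that its members moved apart. The ascending family difference was -10.5 points in cage A, -7.92 in cage B and -1.11 in cage C. In cage A, Faecalibaculum held 22.6% and 25.1% of the ascending counts in control mice and 8.73% to 19.5% in mutant mice. That genus did not pass by edgeR in the ascending colon (log2 -0.36 ± 0.44, adjusted p = 0.708).

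Adjusted p by the exact permutation test was 0.0085 for Akkermansiaceae and Ruminococcaceae, 0.0227 for Bifidobacteriaceae and 0.0468 for Erysipelotrichaceae in the ascending colon, and 0.0227 for each but Bifidobacteriaceae (0.0383) in the descending colon. All 4 families kept 1 direction in 3 of 3 cages in both regions. Muribaculaceae differed by 7.86 ± 4.04 points in the ascending colon and did not pass (adjusted p = 0.232 by the exact permutation test), nor did Lachnospiraceae (adjusted p = 0.5675 by the same permutation test). Bacteroidetes differed by 10.6 ± 4.13 points in the ascending colon and missed the threshold (adjusted p = 0.099, exact permutation test), and Firmicutes differed by -5.47 ± 4.67 points (adjusted p = 0.385, exact permutation test). Bacteroidaceae, the family of Bacteroides, were higher in mutant mice by 1.92 ± 0.81 points in the ascending and 2.29 ± 0.93 in the descending colon. They did not pass in either region (adjusted p = 0.102 and 0.0623, exact permutation test). Actinobacteria, Proteobacteria and Tenericutes did not pass in either region, and Cyanobacteria stayed under the mean share tested. Akkermansiaceae and Ruminococcaceae passed in the ascending colon in each of the 15 fits that left out a mouse, Bifidobacteriaceae in 8 and Erysipelotrichaceae in 7 of them, and in the descending colon Akkermansiaceae passed in 10, Ruminococcaceae and Erysipelotrichaceae in 12 and Bifidobacteriaceae in 7. Without control C2, whose Akkermansia share stood far above the others, the Akkermansiaceae difference was -1.08 points in the ascending and -2.12 points in the descending colon. Of 46 phylum and family tests 10 passed, 3 did without control C1, 4 without control A1 or mutant B1, and 5 without mutant C1.

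**Figure D2:**
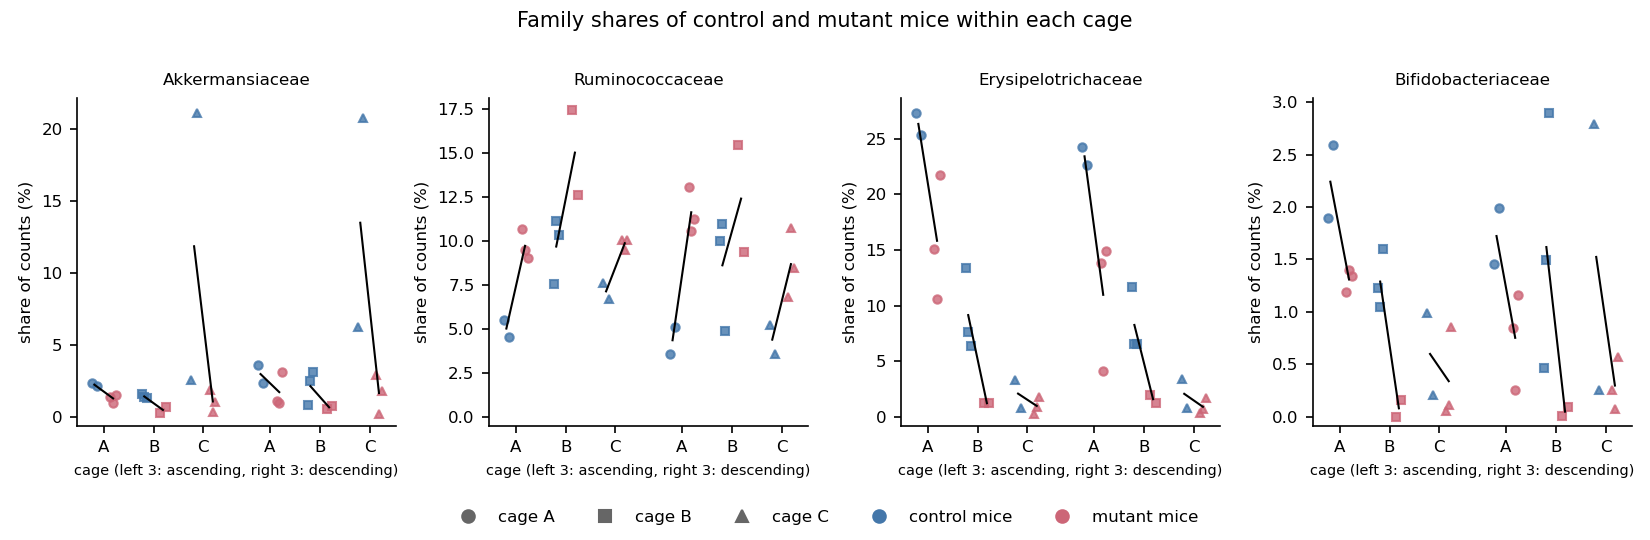
Share of counts (%) of 4 families in each sample, by cage and genotype, for the ascending (left 3 cages) and descending colon (right 3); lines join the mean of the control mice to the mean of the mutant mice of a cage. The line runs in 1 direction in 3 of 3 cages in both regions for each family, from -0.937 points in cage B to -10.8 points in cage C for ascending Akkermansiaceae.

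The fixed lists group the tested ASVs by known traits. Of the 3 tested ASVs of mucin glycan users, 1 rose (ASV11 of Bacteroides) and 0 fell in the ascending colon, and 2 passed when adjusted over the list alone; in the descending colon 0 passed by edgeR, with 3 at an unadjusted p under 0.05 and 3 adjusted over the list alone. As genera its members moved apart in the ascending colon, where Bacteroides was higher and Akkermansia lower in mutant mice, and in the descending colon Akkermansia and Bifidobacterium were lower. Of 202 tested ASVs of butyrate-associated Clostridia, 3 rose (ASV31, ASV32 and ASV15), 2 fell (ASV92 and ASV26) and 5 passed adjusted over the list alone, against 1 of 181 and 0 adjusted over the list alone in the descending colon. Of 11 tested ASVs of the Erysipelotrichaceae group 3 rose and 0 fell in the ascending colon, and 5 passed adjusted over the list alone. In the descending colon 2 of 12 rose, 1 fell and 5 passed adjusted over the list alone, and the summed share of this group fell by 6.76 ± 2.08 points (adjusted p = 0.022, exact permutation test), the 1 list of 11 whose share passed; this call ended without control A1 (0.193), and without control A2, control C1 or mutant B1 (0.055 each). The Muribaculaceae, lactic acid bacteria, Rikenellaceae and Sutterella group held 12, 6, 1 and 1 tested ASVs in the ascending colon, and 0 passed by edgeR, with 2, 0, 0 and 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Mollicutes had 0 of 5 ASVs past the threshold in either region, and 1 lower in mutant mice when adjusted over the list alone. Reagent bacteria held 1 ASV, ASV145 of Staphylococcus, with a lower level in mutant mice in the descending colon. It did not pass there over all ASVs and had an unadjusted p under 0.05 by edgeR. With 1 ASV an adjustment over the list alone changes nothing. Colitis-associated facultative anaerobes held 1 ASV, at 0.00208% ± 0.00394 in ascending control and 0.00359% ± 0.00663 in ascending mutant samples. Signs of diet or host DNA held 1 ASV, with 0.00142% ± 0.00311 of the counts in ascending mutant samples and 0 counts in the other 3 groups.

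Whole-community distances gave a share of 8.97% of the Bray-Curtis variance for genotype in the ascending colon (p = 0.003) and 10.2% in the descending colon (p = 0.002), by exact permutation within cages. Without the cage term these shares were 9.12% (p = 0.244) and 10.4% (p = 0.172) by permutation, and for presence alone in thinned counts the descending share was 5.73% (p = 0.086, exact). The Shannon index was 3.83 ± 0.29 (SD) in ascending control and 3.79 ± 0.24 in ascending mutant samples, and 3.603 ± 0.31 and 3.69 ± 0.27 in the descending colon. ASV richness at 3887 counts was 164.1 ± 20.4 and 151.5 ± 20.1 in the ascending colon and 153.4 ± 17.2 and 140.2 ± 27.8 in the descending colon. None of these 4 genotype differences passed (adjusted p from 0.688 to 0.799, exact permutation tests), and that of descending richness moved from -13.7 to -6.04 without mutant C3.

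The second comparison asked whether the ascending and the descending colon of a mouse held different bacteria. Bacteria of the Mollicutes_RF39 order were lower in the ascending than in the descending colon by 0.0657 ± 0.0175 percentage points (SE, 15 mice), in 12 of the 13 mice that had any difference. Firmicutes differed by 7.57 ± 3.41 points, with higher shares in the ascending colon, and Bacteroidetes differed by -6.76 ± 2.89 points. Muribaculaceae differed by -6.07 ± 2.77 points and were lower in the ascending colon in 12 of 15 mice. Akkermansiaceae differed by -0.687 ± 0.290 points and were lower in the ascending colon in 11 of 15 mice. Rikenellaceae, here the genus Alistipes, were lower in the ascending colon in 8 of 8 mutant mice by 0.676 ± 0.138 points and in 2 of 7 control mice, whose mean difference was 0.223 ± 0.137.

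Of the 23 phylum and family tests over all mice, Mollicutes_RF39 alone passed (adjusted p = 0.0208, exact sign-flip permutation test). Firmicutes, Bacteroidetes, Tenericutes and Verrucomicrobia had an unadjusted p from 0.0228 to 0.0447 and an adjusted p of 0.0671, and Muribaculaceae had an adjusted p of 0.1598, all by exact permutation. The region difference of Rikenellaceae differed between genotypes by -0.932 ± 0.209 points (adjusted p = 0.034, exact permutation test), and this call ended when any mouse but control B2 or mutant B2 was left out (adjusted p 0.0567 to 0.142), with the samples of mouse 12 exchanged (0.119) and on the centred log ratio scale (0.538). As a taxon list, which holds the same 1 ASV, the difference passed (adjusted p = 0.022, exact permutation test), but in 5 of the 15 fits with a mouse left out. Lists were not put on the centred log ratio scale. As the log ratio of the list to all other counts, the difference also passed. In mutant mice alone the region difference of this family did not pass (adjusted p = 0.133, exact sign-flip permutation test). By edgeR its ASV9 had a log2 difference of -0.14 ± 0.20 (ascending over descending) in control mice and -0.17 ± 0.19 in mutant mice, with a difference between genotypes of -0.03 ± 0.28 (adjusted p = 0.976). With the samples of mouse 12 exchanged 5 of the 23 tests passed, as many as without this mouse, and 4 passed without control B1. The Mollicutes_RF39 call ended on the centred log ratio scale (adjusted p = 0.146) and without the mice of both libraries under 10000 counts (0.083).

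**Figure D3:**
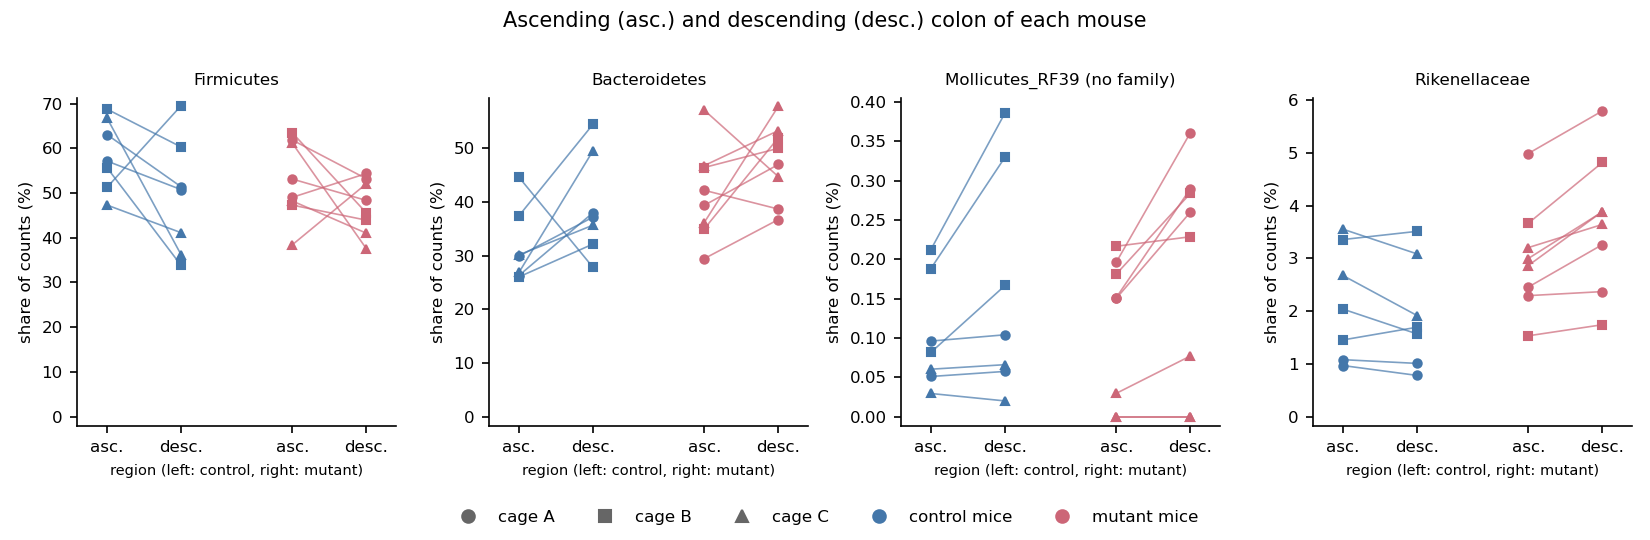
Share of counts (%) of 2 phyla and 2 families in the ascending (asc.) and descending (desc.) colon, with a line per mouse, control mice on the left and mutant mice on the right, and the cage as the symbol. Rikenellaceae were lower in the ascending colon in 8 of 8 mutant mice and 2 of 7 control mice.

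At ASV level 0 of 305 passed between regions by edgeR in control mice (37 at an unadjusted p under 0.05, 0 by DESeq2), 0 in mutant mice (16 unadjusted, 1 by DESeq2), and 0 differed between genotypes in their region effect (18 unadjusted, 0 by DESeq2). The ASVs with the smallest p, which did not pass, were ASV121 of Roseburia (log2 1.83 ± 0.42, ascending over descending), ASV168 of Adlercreutzia (log2 -0.91 ± 0.28) and ASV86 of Erysipelatoclostridium (log2 -1.82 ± 0.58) in control mice, each with an adjusted p of 0.209. In mutant mice they were ASV23 and ASV64, both Lachnospiraceae (log2 1.19 ± 0.31 and 1.49 ± 0.45), and ASV145 of Staphylococcus (log2 1.69 ± 0.49), with an adjusted p of 0.221. For the difference between genotypes they were ASV87 of the Lachnospiraceae, ASV8 of Coriobacteriaceae_UCG-002 and ASV19 of the Muribaculaceae (adjusted p = 0.734). Without control C1 the log2 difference of ASV86 in control mice was -1.15, and without mutant A2 that of ASV145 in mutant mice was 0.75. One ASV passed in control mice without control B1, and 1 in mutant mice without mutant C2. Region took 1.68% of the Bray-Curtis variance (p = 0.0557, exact sign-flip permutation), against 90.9% for the mouse. The mouse term covers 15 mice and also takes up the differences between cages and genotypes. The distance between the regions of a mouse was 0.204 ± 0.090 (SD, n = 7) in control and 0.178 ± 0.067 (n = 8) in mutant mice (p = 0.538, exact permutation test). The Shannon index differed by 0.159 ± 0.096 (SE) and ASV richness by 11.0 ± 8.43 between regions over all mice, with an adjusted p of 0.459 for both by exact permutation; without mutant C3, the mouse of the 3887-count library, the richness difference was 4.92.

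The third comparison asked whether the 3 cages shared 1 microbiota, as the series design states. ASV1 of the Muribaculaceae held 13.4% ± 3.64 (SD, n = 5) of the ascending counts in cage B and 13.4% ± 5.92 in cage C, and 0 counts in cage A. ASV5 of Faecalibaculum, a fermentative member of the Erysipelotrichaceae, held 17.8% ± 6.74 in cage A, 0.00572% ± 0.0128 in cage B and 0.176% ± 0.130 in cage C. ASV17, another Muribaculaceae sequence, held 4.05% ± 1.35 in cage A and 0 counts in cages B and C. ASV16 of the Muribaculaceae held 3.03% ± 0.272 in cage A and 1.69% ± 0.963 in cage B, and 0 counts in cage C. A count of 0 in a cage allows a mean share of up to 0.0112% in cage A, 0.00669% in cage B and 0.0149% in cage C.

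By the F test beside genotype, 131 of the tested ascending and 112 of 245 descending ASVs differed between cages, and DESeq2 called 99 and 84. Adjusted p was 1.25e-08 for ASV5, 1.04e-06 for ASV1, 3.56e-05 for ASV16 and 5.38e-05 for ASV17 in the ascending colon, and 1.93e-07, 1.04e-06, 0.000231 and 8.17e-06 in the descending colon. The others with the smallest p included ASV47 and ASV58 of Lachnospiraceae_NK4A136_group, ASV44 of Dubosiella, ASV55 of Lachnoclostridium, ASV152 of Intestinimonas, ASV82 and ASV90 of Lactobacillus and ASV100 of Mollicutes_RF39. By list, 98 of 202 ASVs of butyrate-associated Clostridia, 6 of 12 Muribaculaceae, 6 of 11 of the Erysipelotrichaceae group and 5 of 6 lactic acid bacteria differed in the ascending colon, with the same numbers adjusted over the list alone. Between pairs of cages, 40 ascending ASVs differed between A and B, 90 between A and C and 90 between B and C. Cages B and C carry 1 strain label. Cage took 57.3% of the Bray-Curtis variance in the ascending and 53.7% in the descending colon (p = 1e-05 for both, the smallest that 100000 permutations can give). Of 370 ASVs 169 were found in all 3 cages, where they held 81.1% ± 3.91 of the counts of cage A, 76.9% ± 3.12 of cage B and 68.0% ± 6.02 of cage C.

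The genotype effect differed between cages for 0 ASVs by edgeR in either region, with 14 ascending and 12 descending ASVs at an unadjusted p under 0.05 and 0 by DESeq2. ASV26 of Eisenbergiella, ASV31 of Ruminococcaceae_UCG-014 and ASV23 of the Lachnospiraceae came closest in the ascending colon (adjusted p = 0.682). With no counts of ASV31 in cage C, its term rests on cages A and B. In the descending colon ASV23, ASV146 of the Lachnospiraceae and ASV13 of Turicibacter came closest (adjusted p 0.218 to 0.747), and 1 ASV passed without mutant A3. Each cage held 2 or 3 mice per genotype.

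**Figure D4:**
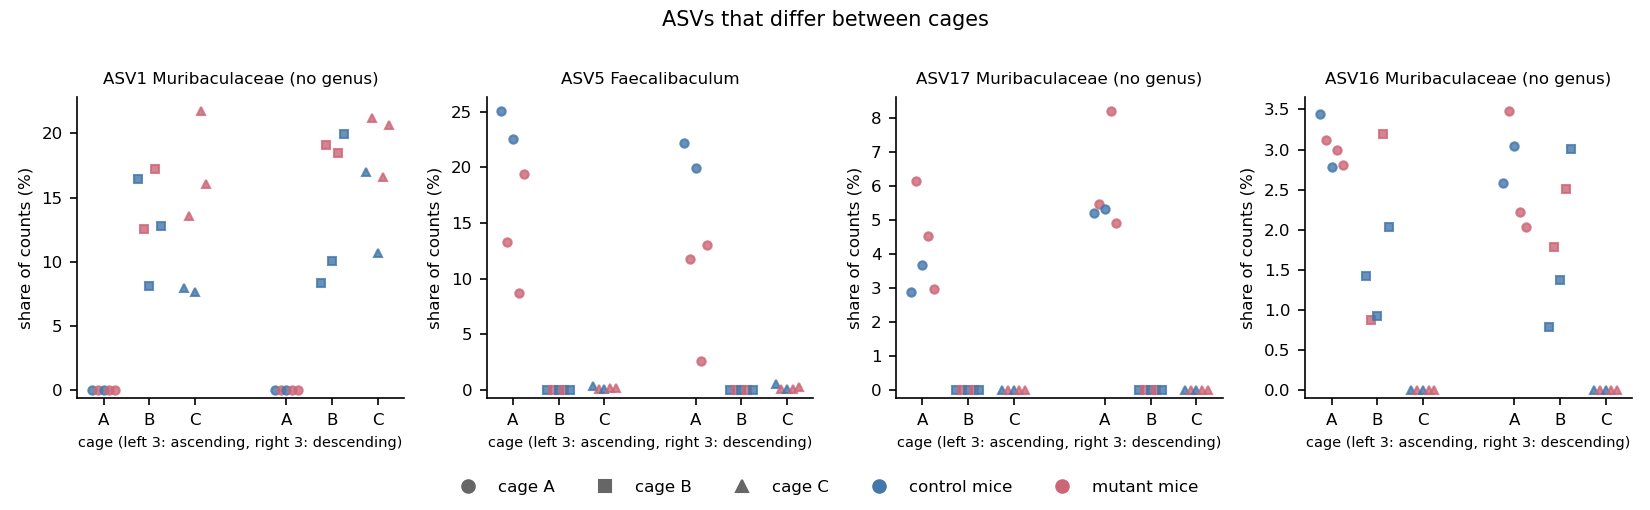
Share of counts (%) of 4 ASVs in each sample by cage, for the ascending (left 3 cages) and descending colon (right 3), with control and mutant mice in different colours. ASV1 had 0 counts in cage A, ASV17 had 0 counts in cages B and C, and ASV16 had 0 counts in cage C.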

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

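The tests of depth, other DNA and a single cage for the family shares, and those of sampling depth and index bleed for the cages, were chosen after their results had been seen. A sample was singled out where its gap to the nearest of its group was large for the range of the group (Dixon's 95% value). Of 132 groups tested, 16 held such a sample, but nested ranks repeat the same values: of 120 different groups 11 held one, and chance gives about 1 in 20, or 6 of them.

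Control C2 held an Akkermansia share of 21.1% of the ascending counts (95% Wilson interval 20.8% to 21.4%), against 1.29% to 2.57% in the other control mice, and of 20.8% of the descending counts (20.4% to 21.1%), against 0.806% to 6.22%. The same values hold for Akkermansiaceae and Verrucomicrobia, which ASV7 of Akkermansia made up. Bacteroides, and with it Bacteroidaceae, stood at 3.83% in the ascending sample of this mouse, against 0.111% to 1.17% in the others. Ruminococcaceae stood at 17.5% in ascending mutant B1, against 9.01% to 12.6%. Lactobacillaceae stood at 16.8% in ascending mutant B2, against 2.173% to 6.55%. Erysipelotrichaceae without a genus name stood at 0.529% in ascending control C1, at 0.374% in its descending sample and at 0.936% in ascending mutant C3. Marvinbryantia stood at 0.293% in descending control C1. Ureaplasma stood at 0.00991% in ascending mutant C3, the only sample of its group with counts, and at 0.0888% in descending control B3. Rikenellaceae were singled out because their region difference differed between genotypes, by -0.932 points in mutant minus control mice, while by edgeR their ASV9 differed by log2 -0.03 ± 0.28.

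The genotype differences in family shares (Akkermansiaceae, Erysipelotrichaceae and Bifidobacteriaceae lower, Ruminococcaceae higher in mutant mice) were weighed against 3 technical explanations. Counting noise from unequal depth is argued against by counts thinned to 3887 in each sample, in which 8 of the 8 family calls of both regions still passed. Thinning leaves a share unchanged on average, so it cannot test an effect of depth before the counts were made. Other DNA among the listed counts is argued against by the summed share of reagent bacteria and of diet or host DNA. This share differed by -0.0268 ± 0.0198 points (p = 0.172, exact permutation test) at most, far below the family differences. The filters used before the table was made are not known, so other DNA in the samples themselves was not tested. A single cage as the cause was set against the sign, which was the same in all cages and both regions for 4 of 4 families. The families were picked by a test over these same cages, and both regions share mice, so equal signs are partly built in. They do not decide whether 1 cage carried most of a difference. Ascending differences in cages A, B and C were 4.70, 5.34 and 2.74 points for Ruminococcaceae, but -0.954, -0.937 and -10.8 for Akkermansiaceae. Within the Erysipelotrichaceae, cage A held nearly all Faecalibaculum counts, while the descending Turicibacter difference was largest in cage B. The genotype stays open as a hypothesis found and tested on these data, beside unequal parts of the cages. Effects of depth before counting and of DNA extraction or amplification, which may differ between taxa, were not tested. Tamoxifen interval and litter are not given per mouse.

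Many ASVs were missing from a whole cage, as ASV1 of the Muribaculaceae from cage A. Sampling at limited depth is argued against for 73.7% of the 316 pairs of a missing ASV and a cage, with 3 or more counts expected per library. Over the whole cage 96.5% of the pairs had 3 or more expected. That share was largely built in, since a count of 1 is never listed and the cages had similar totals (446813 to 525130 counts). The expected counts take an ASV as spread evenly over mice, while 32 of the 370 ASVs had counts in 1 sample only. Index bleed between libraries is argued against as the source of the ASV5 counts of Faecalibaculum in cage C, since the rate of ASV1 in cage A, with a floor of 3 counts per library, was at most 0.0323 of theirs, but it stays open for the lower ASV5 counts of cage B, where the floor lies at 3.05 times their rate. Near-identical variants that stand in for each other remain open, since 4 of 36 missing ASVs (11.1%) had a variant within 2 bases in the cage that lacked them, just above the limit of 0.1 of them set before. Cages B and C carry 1 strain label and still differed in 90 of 234 ascending ASVs, with 69 ASVs found in cage C alone, which argues against the strain tag as the whole cause, while cage and age, and the strain tag for the 30 ASVs missing from cage A alone, cannot be told apart.

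The sample codes of mouse 12 (mutant C2) go against its titles, and an exchange of its samples between regions was tested by its profile of ascending minus descending levels over 337 ASVs. The profile correlated with the mean of the other mice at r = -0.0908, below 0 as an exchange predicts, while 12 of the 14 other mice lay above 0. The evidence is weak, since the other mice ran from -0.177 (control B1, whose codes match its titles) to 0.159 with a median of 0.0803. These values allow an exchange but do not decide it. With the exchange, 5 of 23 region tests of phyla and families passed instead of 1, as many as without this mouse. By its codes mouse 12 gave a cecum and a distal colon sample, so the exchange puts a cecum-coded sample in the ascending group. If the codes hold, this mouse has no ascending colon sample in either order.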

How the results depend on the processing

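The tests without the mice of both libraries under 10000 counts were chosen after the data had been seen. Among results that answer a comparison, 490 values under alternatives were labelled the same, 70 weaker, 23 stronger, 3 moved and 5 reversed. Among single taxa these numbers were 1623, 399, 11, 14 and 2. Counts of calls were the same within a fixed ratio of the main count. Tested values were the same where they kept direction and side of the threshold, and reversed where the direction changed. Shares, diversity and distances in a single cage were the same within the SD of the main value and moved beyond it. They were reversed only where the main value passed. The cause was not tested for any change below, except that single cages hold fewer mice. Genotype calls among ascending ASVs (9) came to 5 with TMM factors, 1 with no filter, 5 without the shallow mice, 2 with no cage term, 0 with the replicate block, and 4, 2 and 0 in cages A, B and C alone. Descending ASVs (4) came to 8 by total count alone, 1 with no filter, 2 without the shallow mice, 1 with no cage term, 0 with the block, and 0, 1 and 0 in the cages. Summed ASVs (2) came to 10 with TMM factors, 5 by total count alone, 10 by DESeq2, 9 with the stricter filter, 5 without the shallow mice, 0 with the block and 0 in each cage. Ascending genera (12) came to 6 by DESeq2, 7 without the shallow mice, 2 with no cage term, 3 with the block, 4 in cage B and 1 in cage C. Descending genera (7) came to 12 by DESeq2, 4 with the block, and 4, 2 and 0 in the cages. By edgeR with total count alone 2 ASVs passed between regions in control mice, and by DESeq2 1 in mutant mice, against 0. Cage calls (131 and 112) came to 65 and 61 with the stricter filter, and 1 descending genotype by cage term passed without the shallow mice. Region calls of phyla and families (1) came to 5 with the samples of mouse 12 exchanged, 0 by centred log ratio and 0 without the shallow mice. The list call (1) came to 0 by the log ratio of a list to all other counts. The genotype share of Bray-Curtis variance no longer passed without the cage term (9.12%, p = 0.244, and 10.4%, p = 0.172, by permutation) or, in the descending colon, by Jaccard distance (5.73%, p = 0.0860, exact test). The Shannon difference was 0.00879 in the ascending colon with mouse 12 exchanged and 0.245 in cage A, and 0.446 and -0.224 in cages A and B in the descending colon. ASV168 of the region in control mice reversed in cage A (log2 0.218), and ASV87 of the region by genotype difference in cage B (-0.0802).

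With each mouse left out in turn, the genotype counts ran from 1 to 11 (ascending ASVs), 0 to 8 (descending), 1 to 5 (summed), 6 to 14 (ascending genera) and 2 to 8 (descending genera). Ascending ASVs came to 1 without control A1, B2 or C1 or mutant A1 or A2, 2 without control A2 or mutant B2, and 4 without control B1 or B3. Phylum and family calls ran from 3 (control C1) to 11 by genotype, with 4 without control A1 or mutant B1 and 5 without mutant C1, and from 1 to 5 by region, with 4 without control B1 and 5 without mutant C2. The region count ran from 0 to 1 in control mice (control B1) and in mutant mice (mutant C2), and the descending genotype by cage count from 0 to 1 (mutant A3). List calls ran from 0 to 3, with 0 without control A2 or C1, 2 without control B1 or mutant B1 or B2, and 3 without control B3. The ascending Shannon difference ran from -0.103 to 0.0661, above 0 without control C1, mutant B2 (0.0467) or mutant C2 (0.0173), and the difference in distance between regions from -0.0548 to 0.00289 (control C1). Depth limited the absences: 3 counts per library came to mean shares of 0.0112% in cage A and 0.0149% in cage C.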

Other observations

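The tests on other splits of the samples were planned, and the genera of the next paragraph were chosen after their values had been seen and were not tested here.

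Genera of the Erysipelotrichaceae had different mean shares in the 3 cages. Faecalibaculum averaged 17.8% ± 6.74 (SD, n = 5) of the ascending counts in cage A, 0.0155% ± 0.0106 in cage B and 0.1755% ± 0.130 in cage C. Dubosiella averaged 1.44% ± 0.658 in cage A and had 0 counts in cages B and C. Turicibacter averaged 5.50% ± 5.53 in cage B, 0.7174% ± 0.981 in cage C and 0.282% ± 0.116 in cage A. Of the Atopobiaceae, Coriobacteriaceae_UCG-002 averaged 4.78% ± 1.24 in cage A, 1.87% ± 1.52 in cage B and 1.32% ± 0.864 in cage C. Oscillibacter was higher in the ascending than in the descending colon in 13 of 15 mice, with 1.38% ± 0.746 against 0.7855% ± 0.6735 in control mice (n = 7) and 0.965% ± 0.6655 against 0.620% ± 0.349 in mutant mice (n = 8); this difference was not tested.

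The 2 samples of a mouse resembled each other most. The nearest sample by Bray-Curtis distance came from the same mouse for 23 of 30 samples and from the same cage for 30 of 30. The median distance was 0.177 between the regions of a mouse, 0.321 between mice of 1 cage, genotype and region, 0.370 between genotypes within a cage and region, and 0.530 between cages within a genotype and region.

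Other splits of the same samples were drawn to see whether chance can be excluded as the source of each count, with the real split included. For genotype in the ascending colon, 1 of 100 splits within cages gave as many ASVs as the real 9, and the highest other gave 1. For genera, 1 of 100 gave as many as 12 in the ascending colon (highest other 6) and 1 of 100 as many as 7 in the descending colon (highest other 3). For descending ASVs 2 of 100 gave 4 or more, the highest other giving 5, and for the sum per mouse 2 of 100 gave 2, the highest other giving 2. Taken alone, each of these 5 counts was reached by 1 or 2 of the 100 splits drawn, under the level of 0.05. For ascending ASVs and for the genera of both regions, no other split drawn reached the real count, which argues against chance. For descending ASVs and the sum per mouse another split did, so chance is less firmly excluded there. Not every possible split was drawn, the 5 counts come from the same mice, and no adjustment was made over the results tested in this way. For cages, 1 of 100 splits gave as many as 131 ascending ASVs (highest other 12) and 1 of 100 as many as 112 descending ASVs (highest other 2), so chance can be excluded. For the counts of 0 the splits test nothing, since any split gives as many: 64 of 64 for the region in control mice (highest other 10), 100 of 100 for the region in mutant mice (highest other 0), 100 of 100 for the region by genotype difference (highest other 22), and 100 of 100 for the genotype by cage terms in the ascending (highest other 1) and in the descending colon (highest other 6). The splits that called 10 ASVs for the region in control mice and 22 for the region by genotype difference may point to a structure of the samples, which was not tested.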
